A study of Mus musculus with 6 samples.

How the data were processed

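Total RNA of mouse yolk sac at E16.5 was extracted with TRIzol and sequenced on an Illumina instrument, per the labels' protocols, in 3 wild-type and 3 Rsu1-/- samples. Groups and replicate numbers were taken from the sample titles. The authors deposited a matrix of raw read counts per Ensembl gene and, per sample, a signal value per gene. The submitters' processing notes name Bowtie 0.12.2 and the genome builds mm8, GRCm38 and mm10, without saying which served which step. The read counter, the annotation, the filters and whether counting used strand are not given in the sources used here, so reads of overlapping or antisense genes cannot be assigned with certainty.

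The matrix held whole numbers for 55487 genes and was used as deposited. The deposited signal values were the same counts divided by 1 factor per library. Multiplying back gave whole reads for 100% of values within a tolerance of 0.001, equal to the matrix for all 55487 genes, and the factors equalled median-of-ratios size factors. Gene symbols and coordinates came from GENCODE M21 on GRCm38, matched by Ensembl identifier: 55227 identifiers had a symbol and 260 did not. Library totals were 17859671 to 19450982 counts. No pair of libraries agreed within sampling noise, with chi-square per degree of freedom of at least 25.8.

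Counts were filtered with filterByExpr (minimum count 10, minimum total count 15), leaving 15610 genes, scaled with TMM and tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test on genotype over all 6 libraries. P-values were adjusted by Benjamini and Hochberg over the tested genes, with a threshold of 0.05. Standard errors were taken as the log2 fold change divided by the square root of F. The common dispersion was 0.0707, a biological coefficient of variation of 26.6%. Levels are CPM on TMM-scaled library sizes.

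Pathway and cell type lists, 46 in number, were fixed before the data were examined, as were the test, its design and the rule for named genes. Lists of pathway and cell type genes with at least 3 tested members, 42 in all, were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, and adjusted over the lists. The test was repeated with a correlation estimated from the data and with fry. Named genes were Rsu1, then the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 5 CPM in the higher group, groups that did not overlap and a symbol other than a Gm number or Rik. Then came up to 4 members of each described list with the smallest p, with those that missed the threshold given as values only. Other genes are said to be chosen after their values were seen, or belong to a described complex, list or neighbourhood.

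Simulated counts with known changes were used to test the procedure on 15610 genes for this comparison. The edgeR test recovered 29% of 100 genes changed 2-fold and 82% of 100 changed 4-fold, with 8 false calls among 119. DESeq2 recovered 58% and 84%, with 45 false calls among 187. In simulated lists the preset correlation and fry each found both shifted lists of 2, and the estimated correlation found 1. Simulated genes were drawn independently of each other, so this does not test the preset correlation on lists whose members vary together. In the data the estimated correlation was 0.577 for the interferon list and 0.0219 for the matrix protease list.

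Alternatives planned beforehand were other scalings, DESeq2 1.42.0, limma-voom, a robust fit, other filters, removal of globin and mitochondrial genes, a replicate block, a 2-fold threshold, omission of genes on X and Y, and leaving out each library. A correction for transcript length, a fit to the recovered reads and list and solute carrier counts without single libraries were added after seeing the data. The test of the endoderm share moved the edgeR null over log2 shifts from −1.5 to 0.5, common to all members, and counted members apart from each, with and without markers shared with other epithelia and members past the threshold. Intervals of medians in the closing tests are 95% bootstrap intervals from 10000 resamples of genes (1000 for the correlation with length), which are not independent of each other.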

Results

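RNA was sequenced from mouse yolk sac at E16.5, late in gestation, in 3 wild-type and 3 Rsu1-/- samples of the C57BL/6 strain. The yolk sac is the extraembryonic membrane in which a visceral endoderm epithelium takes up and exports nutrients over a layer of mesoderm with blood vessels and mesothelium. Rsu1 encodes Ras suppressor 1, a leucine-rich repeat protein that binds PINCH1 in the complex of integrin-linked kinase (ILK), PINCH and parvin at focal adhesions. The comparison asks how the yolk sac transcriptome differs between the genotypes. Library totals ranged from 17859671 to 19450982 counts over 55487 genes, of which 15610 had enough counts to be tested. The labels do not say whether the samples of a group came from separate litters or embryos, so p-values measure the spread between these samples.

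Rsu1 was lower in all 3 Rsu1-/- libraries. It had 29.6 ± 2.55 CPM (counts scaled to library size, mean ± SD, n = 3) in wild type and 11.8 ± 1.45 in Rsu1-/-, a 2.52-fold lower level (log2 fold change −1.33 ± 0.16 SE, adjusted p = 0.0184, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Raw counts were 613, 491 and 547 in wild-type replicates 1 to 3 and 225, 201 and 217 in the Rsu1-/- replicates. The gene (ENSMUSG00000026727) spans chromosome 2, 13076821 to 13271415, in GRCm38, and counts cover its exons as a whole, so they do not show which exons the remaining reads came from. Its neighbour Cubn, the endocytic receptor cubilin at 13276338 to 13491813, had a log2 fold change of −0.79 ± 0.23 (adjusted p = 0.108, edgeR), which missed the threshold. Of 86 genes tested within 10 Mb of Rsu1, 2 changed, Rsu1 included. The Rsu1 call was lost without wild-type replicate 1 (adjusted p = 0.0863, edgeR) and without Rsu1-/- replicate 3 (adjusted p = 0.0551), while the log2 fold change stayed between −1.38 and −1.24 whichever library was left out.

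**Figure D1:**
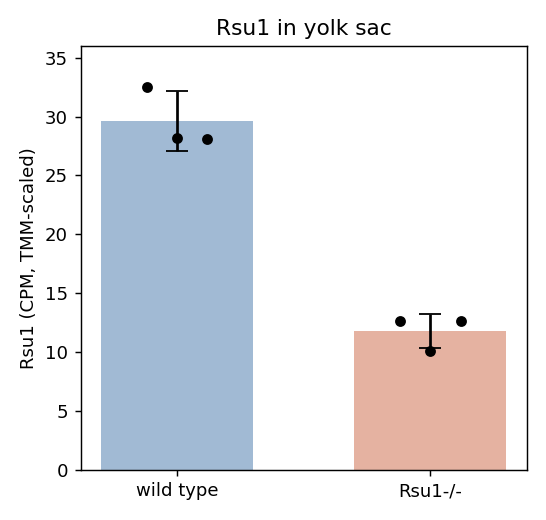
Rsu1 level in CPM (y axis, TMM-scaled) in wild-type and Rsu1-/- yolk sac. Bars are means, error bars the SD of 3 libraries and points single libraries. All 3 Rsu1-/- libraries, at 10.1 to 12.6 CPM, lie below the wild-type libraries, at 28.1 to 32.6 CPM.

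Between the genotypes 434 genes changed at an adjusted p below 0.05 in edgeR's quasi-likelihood test, 249 higher and 185 lower in Rsu1-/-. A change of at least 2-fold was found for 225 of the higher and 123 of the lower genes. The 3 values of one group did not overlap those of the other for all 434 genes, and for 26.6% of all tested genes, against 10% by chance. The count rested on single libraries: it was 0 without wild-type replicate 1, where 2532 genes had an unadjusted p below 0.05, and 32 without Rsu1-/- replicate 3. It was 224, 129, 245 and 173 without wild-type replicates 2 and 3 and Rsu1-/- replicates 1 and 2. All 434 genes kept their sign in each of these fits. Groups that do not overlap all but fix this in advance, so it does not show that the calls are stable. Rsu1-/- replicate 3 was the only library with Xist (18828 counts) and the only 1 with 0 counts of the Y-linked genes Ddx3y, Eif2s3y and Uty.

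The 12 largest rises ranged from 20.2-fold to 90.8-fold. Wnt7a, a secreted WNT ligand, was 90.8-fold higher (log2 fold change 6.50 ± 1.23 SE, adjusted p = 0.0407, edgeR), from 10 counts over the wild-type libraries to 883. Of 4 chemokine genes among them, Cxcl1 was 56.7-fold higher (5.83 ± 0.73), Ccl2 45.4-fold (5.51 ± 0.64), Cxcl10 28.6-fold (4.84 ± 0.65) and Ccl7 20.2-fold (4.34 ± 0.73). Serpine1 (chromosome 5, 137061504 to 137072268), the plasminogen activator inhibitor PAI-1, went from 43.2 ± 27.5 CPM to 1150 ± 861 CPM (26.6-fold, adjusted p = 0.0272), and Serpina3n, an acute-phase protease inhibitor, rose 46.9-fold. The serine proteases Prss22 and Prss27 rose 35.0-fold and 23.0-fold. Il11, a cytokine of the interleukin-6 family, Hmga2, a chromatin-binding protein of embryonic tissue, and Rgs16, a regulator of G-protein signalling, completed the 12 largest rises (34.4-fold, 25.4-fold and 21.7-fold; all edgeR). Several of these sizes depended on 1 library. Without Rsu1-/- replicate 3 the log2 fold change was 5.35 for Wnt7a, 3.99 for Serpine1 and 3.42 for Hmga2. Without Rsu1-/- replicate 2 it was 4.86 for Serpina3n and 3.87 for Il11. Without wild-type replicate 1 it was 7.20 for Wnt7a, 7.08 for Prss22, 5.41 for Prss27 and 5.34 for Ccl7, and without wild-type replicate 3 it was 5.92 for Rgs16.

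The 12 largest falls ranged from 4.04-fold to 7.28-fold and included 2 transporters and 4 metabolic enzymes. Slc36a2, a transporter of small amino acids, was 7.28-fold lower (log2 fold change −2.86 ± 0.58, adjusted p = 0.0472), and Slc2a2, the glucose transporter GLUT2, 4.63-fold lower (−2.21 ± 0.25, adjusted p = 0.017). Among enzymes, Tdh (threonine dehydrogenase) fell 6.87-fold, Cps1 (carbamoyl-phosphate synthase of the urea cycle) 6.15-fold and Prodh2 (hydroxyproline dehydrogenase) 5.28-fold. Enpp7, the alkaline sphingomyelinase of absorptive epithelium (ENSMUSG00000046697, chromosome 11, 118988188 to 118993221), had the smallest p of the 12, with 26.5 ± 2.23 CPM in wild type and 5.82 ± 0.757 CPM in Rsu1-/- (4.55-fold lower, adjusted p = 0.00885, edgeR). Prkg2, a cGMP-dependent protein kinase, fell 5.01-fold, Snhg11 4.57-fold, Ttn (titin) 4.40-fold and Paqr9 4.33-fold. Tubal3, an alpha-tubulin-like gene, and Ccdc13 fell 4.14-fold and 4.04-fold. Without Rsu1-/- replicate 2 the log2 fold change of Cps1 was −3.38, and without wild-type replicate 1 that of Prodh2 was −1.73 and its call was lost.

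**Figure D2:**
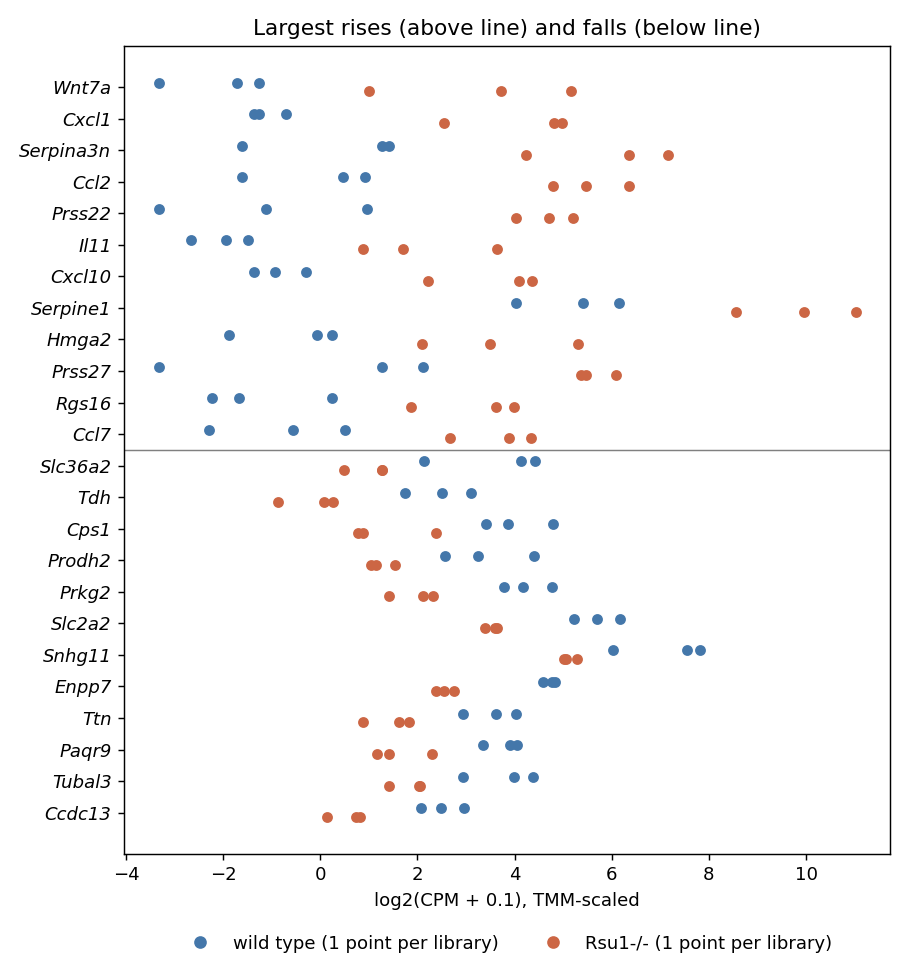
Levels of the 12 largest rises and 12 largest falls (y axis, gene symbols) as log2 of CPM plus 0.1 (x axis), 1 point per library, wild type in blue and Rsu1-/- in orange. In each gene the 3 points of one genotype lie to one side of the 3 points of the other, which the naming rule required. The Rsu1-/- points spread widely for genes such as Wnt7a and Serpine1.

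Part of the interferon-response, cytokine and macrophage genes rose in Rsu1-/-. Of 24 interferon-response genes 11 rose and none fell (20 rose when adjusted over the list alone), with a median log2 fold change of 1.37 (camera adjusted p = 4.19e-12, but adjusted p = 0.257 with an estimated correlation). Ifi44 had the smallest p of all genes (ENSMUSG00000028037, chromosome 3, 151730922 to 151749960), going from 2.49 ± 0.388 to 21.6 ± 2.21 CPM (8.65-fold, adjusted p = 0.00664, edgeR). The interferon regulatory factor Irf7 rose 3.26-fold, the guanylate-binding protein Gbp2 2.48-fold and Ifit1 4.66-fold. Among 19 inflammatory cytokine and NF-κB genes 8 rose (13 when adjusted over the list alone; camera adjusted p = 5.15e-08, adjusted p = 0.257 with an estimated correlation), among them Ptgs2, the inducible cyclooxygenase (15.1-fold; log2 fold change 3.13 without Rsu1-/- replicate 3). The median log2 fold change of the cytokine list was 2.0, and 1.00 without Rsu1-/- replicate 3, where the interferon median was 1.55. Of 22 macrophage markers 7 rose and none fell (13 when adjusted over the list alone; camera adjusted p = 5.15e-08, adjusted p = 0.257 with an estimated correlation). These included Fcgr1, the high-affinity Fc receptor (4.12-fold, adjusted p = 0.0128), lysozyme Lyz2 (3.34-fold) and the complement genes C1qb and C1qc (2.21-fold and 2.26-fold). Of 24 complement and coagulation genes C1qa, C1qb, C1qc and the C1 inhibitor gene Serping1 rose (7 rose and 2 fell when adjusted over the list alone), with no call of the list (camera adjusted p = 0.485), a mean log2 fold change of 0.20 and a median of −0.21 that turned positive without wild-type replicate 2 (0.03) or Rsu1-/- replicate 2 (0.05). Without Rsu1-/- replicate 3, 2 interferon, 1 cytokine and 2 macrophage genes passed, and without wild-type replicate 1 none did.

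Some matrix genes and targets of YAP-TAZ and TGF-β signalling also rose. Of 24 YAP-TAZ and TGF-β target genes 5 rose and none fell (15 when adjusted over the list alone; camera adjusted p = 5.15e-08, adjusted p = 0.257 with an estimated correlation), with Ltbp2 9.13-fold, Ccn2 8.76-fold and Amotl2 1.78-fold higher. Ccn2 shares 23.2% of its exonic bases with an overlapping gene, which leaves its count uncertain. Of 19 matrix proteases and inhibitors 5 rose (10 when adjusted over the list alone; camera adjusted p = 7.00e-06, adjusted p = 0.257 with an estimated correlation), including the protease inhibitor Timp1 (12.1-fold) and the plasminogen activators Plau (3.70-fold) and Plat (9.89-fold). Of 23 fibrillar collagen and mesenchymal matrix genes Fbln2, the collagen cross-linking enzyme Lox and Bgn rose (7.62-fold, 4.30-fold and 1.85-fold), and 20 did not pass (5 rose when adjusted over the list alone; camera adjusted p = 8.28e-06, adjusted p = 0.282 with an estimated correlation). Wild-type replicate 2 had low levels of this list (Col1a1 1342 CPM against 6161 and 4594 in the other wild-type libraries), and without it no member passed. Without Rsu1-/- replicate 3 the log2 fold change was 2.18 for Ccn2 and 2.31 for Fbln2, and without Rsu1-/- replicate 2 it was 2.62 for Plat.

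Adhesion and actin lists were called higher with the preset correlation, while no gene of the complex to which Rsu1 binds passed the test. Of 26 ILK-PINCH-parvin and focal adhesion genes 0 passed over all genes and 5 rose when adjusted over the list alone (median log2 fold change 0.20; camera adjusted p = 0.00425, adjusted p = 0.257 with an estimated correlation). The log2 fold changes were 0.18 ± 0.19 for Ilk, 0.31 ± 0.14 for Lims1, which encodes PINCH1, and 0.12 ± 0.17 for Parva. The largest departures were those of Fermt1 (2.21 ± 0.51, adjusted p = 0.0635, edgeR) and the actin cross-linker Actn1 (1.17 ± 0.29, adjusted p = 0.0723). Fermt1 is also on the amnion and epidermis list described below, so its value is not separate from that list. Among 22 integrins Itgb6, the epithelial β6 subunit, rose 3.86-fold (adjusted p = 0.0195, edgeR) and 21 did not pass (6 rose when adjusted over the list alone; camera adjusted p = 0.00266, adjusted p = 0.282 with an estimated correlation). Of 26 actin cytoskeleton and Rho signalling genes 0 passed and 23 had positive log2 fold changes (4 rose when adjusted over the list alone; median log2 fold change 0.37; camera adjusted p = 0.000261, adjusted p = 0.282 with an estimated correlation). Tropomyosin Tpm1 had a log2 fold change of 0.94 (adjusted p = 0.0524, edgeR) and moesin, Msn, 1.16 (adjusted p = 0.0526). Of 22 basement membrane genes 0 passed and 18 had positive log2 fold changes (1 rose when adjusted over the list alone; camera adjusted p = 0.00413, adjusted p = 0.282 with an estimated correlation), with 2.10 for the laminin chain Lamc2 (adjusted p = 0.0591, edgeR). Among 19 Ras-ERK feedback targets Ier3, Dusp7 and Epha2 rose (3.70-fold, 3.49-fold and 2.62-fold) and Etv5 fell 2.06-fold (8 rose and 1 fell when adjusted over the list alone; camera adjusted p = 1.88e-05, adjusted p = 0.257 with an estimated correlation). Of 23 immediate early and AP-1 genes Fos and Egr1 rose, 2.04-fold and 7.10-fold (15 rose when adjusted over the list alone; camera adjusted p = 4.82e-07, adjusted p = 0.262 with an estimated correlation). Of 21 heat shock and oxidative stress genes 0 passed, also when adjusted over the list alone, and 15 had positive log2 fold changes (camera adjusted p = 0.0331, adjusted p = 0.32 with an estimated correlation). Their median was 0.41, 0.22 without Rsu1-/- replicate 3 and 0.27 without wild-type replicate 1, and the call was lost without either (adjusted p = 0.0594 and 0.0967) and without Rsu1-/- replicate 1 (0.0775) or with the filter on CPM above 1 (0.0551). All 28 cytosolic ribosomal protein genes had positive log2 fold changes, with a median of 0.30, and 0 passed, also when adjusted over the list alone (camera unadjusted p = 4.75e-06, unadjusted p = 0.363 with an estimated correlation).

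Some keratin and squamous epithelium genes rose in Rsu1-/-. Of 21 genes of the amnion and epidermis list Krt14, Krt17 and Sfn rose and 18 did not pass (8 rose when adjusted over the list alone; camera adjusted p = 8.01e-07, adjusted p = 0.257 with an estimated correlation). Krt14 (chromosome 11, 100203162 to 100207548) went from 20.5 ± 5.10 to 205 ± 100 CPM (9.99-fold, adjusted p = 0.0189, edgeR), Krt17 rose 5.37-fold and the epithelial 14-3-3 gene Sfn 3.02-fold. Krt5, the usual partner of Krt14, had 60.1 ± 52.0 CPM in wild type and 158 ± 68.4 CPM in Rsu1-/- and did not pass. Among 12 mesothelium markers Bnc1, Msln and Igfbp5 rose about alike (2.05-fold, 1.93-fold and 2.12-fold; 4 rose when adjusted over the list alone; camera adjusted p = 0.019, adjusted p = 0.257 with an estimated correlation). The deviation of wild-type replicate 2 from the mean of all libraries was −2.86 log2 units on the amnion list and −1.07 on the mesothelium list, as means over members. Without it 2 amnion genes and no mesothelium gene passed, and camera's call of the mesothelium list was lost without Rsu1-/- replicate 2 (adjusted p = 0.104).

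Visceral endoderm genes fell in part. Of 26 markers Gata4, a transcription factor of the endoderm, Slc2a2 and the endocytic receptor Lrp2 (megalin) fell and 23 did not pass (3 rose and 8 fell when adjusted over the list alone; camera adjusted p = 0.0204, adjusted p = 0.303 with an estimated correlation). Camera's call of this list was lost without wild-type replicate 2 (adjusted p = 0.0579), wild-type replicate 3 (0.0662) or Rsu1-/- replicate 2 (0.139). Gata4 went from 37.2 ± 6.41 to 13.1 ± 0.329 CPM (2.83-fold lower, adjusted p = 0.0161, edgeR) and Lrp2 from 1688 ± 129 to 873 ± 140 CPM (1.93-fold lower, adjusted p = 0.0373). The most abundant markers did not pass: the log2 fold change was −0.27 ± 0.29 for Afp, −0.21 ± 0.27 for Trf and 0.10 ± 0.27 for Apoa1, 3 genes chosen after their values were seen. Apob, the structural protein of lipoproteins, had a log2 fold change of −1.36 ± 0.28 (adjusted p = 0.0508). Of 25 endocytosis and lysosome genes only Lrp2 fell (5 when adjusted over the list alone; camera adjusted p = 3.51e-05, adjusted p = 0.282 with an estimated correlation), and 22 had negative log2 fold changes. Of 25 nutrient and ion transporters Slc2a2 and the phosphate transporter Slc34a2 (1.98-fold lower) fell and 23 did not pass (12 fell when adjusted over the list alone; median log2 fold change −0.66, and −0.41 without wild-type replicate 2; camera adjusted p = 0.000142, adjusted p = 0.262 with an estimated correlation). Of 22 lipoprotein genes Apoa2 fell 2.27-fold (4 fell when adjusted over the list alone; camera adjusted p = 0.027, adjusted p = 0.257 with an estimated correlation). Of 16 bile acid, vitamin and xenobiotic genes Cyp27a1, a sterol 27-hydroxylase, fell 2.09-fold and Rdh10, a retinol dehydrogenase, rose 2.66-fold (2 rose and 6 fell when adjusted over the list alone), with no call of the list (camera adjusted p = 0.413). None of these falls of endoderm, endocytosis, transporter and lipoprotein genes passed without Rsu1-/- replicate 3 or without wild-type replicate 1.

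Definitive erythroid genes were low in Rsu1-/- replicates 1 and 3, and none passed over all genes. The mean deviation of the list from the mean of all libraries was −1.16 and −1.31 log2 units in these and 0.18 in Rsu1-/- replicate 2, against 0.56, 0.42 and 1.30 in wild-type replicates 1 to 3. Of 18 tested 8 fell when adjusted over the list alone, and the median log2 fold change was −1.83 (camera adjusted p = 9.11e-06, adjusted p = 0.282 with an estimated correlation). Globin transcripts made up 0.306%, 0.267% and 0.633% of counts in wild-type replicates 1 to 3 and 0.0488%, 0.191% and 0.0391% in the Rsu1-/- replicates. The near-identical copies Hba-a1 and Hba-a2, like Hbb-bs and Hbb-bt, share reads, so their separate counts are uncertain; Hba-a1 had a log2 fold change of −2.34 ± 0.66 (adjusted p = 0.0997, edgeR). Among 18 iron and haem genes the transferrin receptor Tfrc fell 2.38-fold and Fech, the last enzyme of haem synthesis, 1.51-fold, while the iron hormone gene Hamp rose from 4 counts over the wild-type libraries to 78. Adjusted over the list alone, 4 rose and 5 fell, and camera gave no call (adjusted p = 0.868).

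Endothelium, smooth muscle, VEGF and Notch signalling, cell cycle, p53, unfolded protein response, hypoxia, cholesterol synthesis and trophoblast lists had no member past the threshold and no call by camera, with adjusted p from 0.0607 for cholesterol synthesis to 0.832 for the cell cycle. Adjusted over the list alone, 2 p53 genes rose and no member of the other lists passed. Some of these lists were called when 1 library was left out. Endothelium was higher without wild-type replicate 2 (adjusted p = 0.0487) or Rsu1-/- replicate 3 (0.0346), smooth muscle without wild-type replicate 1 (0.0396) and VEGF and Notch without Rsu1-/- replicate 3 (0.0343). Hypoxia was higher without wild-type replicate 3 (0.000202) or Rsu1-/- replicate 2 (0.012) and with the replicate number as a block (0.0371), cholesterol synthesis lower without wild-type replicate 1 (0.00582) or Rsu1-/- replicate 1 (0.000422), and the cell cycle lower without wild-type replicate 2 (0.0097). The median log2 fold change over 25 endothelial markers was 0.10, 0.31 without wild-type replicate 2, 0.26 without Rsu1-/- replicate 3, −0.13 without Rsu1-/- replicate 2, −0.06 without wild-type replicate 3 and −0.02 without wild-type replicate 1. Over 28 cell cycle genes it was −0.03 and ranged from −0.27 without wild-type replicate 2 to 0.27 without wild-type replicate 1, so neither list had a stable direction. The median also changed sign for hypoxia (0.12, and −0.059 without wild-type replicate 2) and cholesterol synthesis (−0.17, and 0.019 without Rsu1-/- replicate 2). So did those of the unfolded protein response (0.16, and −0.048 without Rsu1-/- replicate 3) and smooth muscle (0.13, and −0.0079 without wild-type replicate 3). Medians of the VEGF and Notch, p53 and trophoblast lists kept their sign. Of 26 nuclear-encoded oxidative phosphorylation genes 0 passed, also when adjusted over the list alone, and 22 had negative log2 fold changes (median −0.15, and −0.10 without wild-type replicate 3; camera adjusted p = 0.0156, adjusted p = 0.381 with an estimated correlation). That call was lost without wild-type replicate 3 (adjusted p = 0.122), Rsu1-/- replicate 1 (0.0931) or Rsu1-/- replicate 2 (0.06). In total 21 of 42 lists were called higher and 8 lower with camera's preset correlation. Some lists shared members, such as Slc2a2, Lrp2, Plat and Serpine1, so these calls are not independent of each other. None of these calls held with an estimated correlation, where the smallest adjusted p was 0.257.

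**Figure D3:**
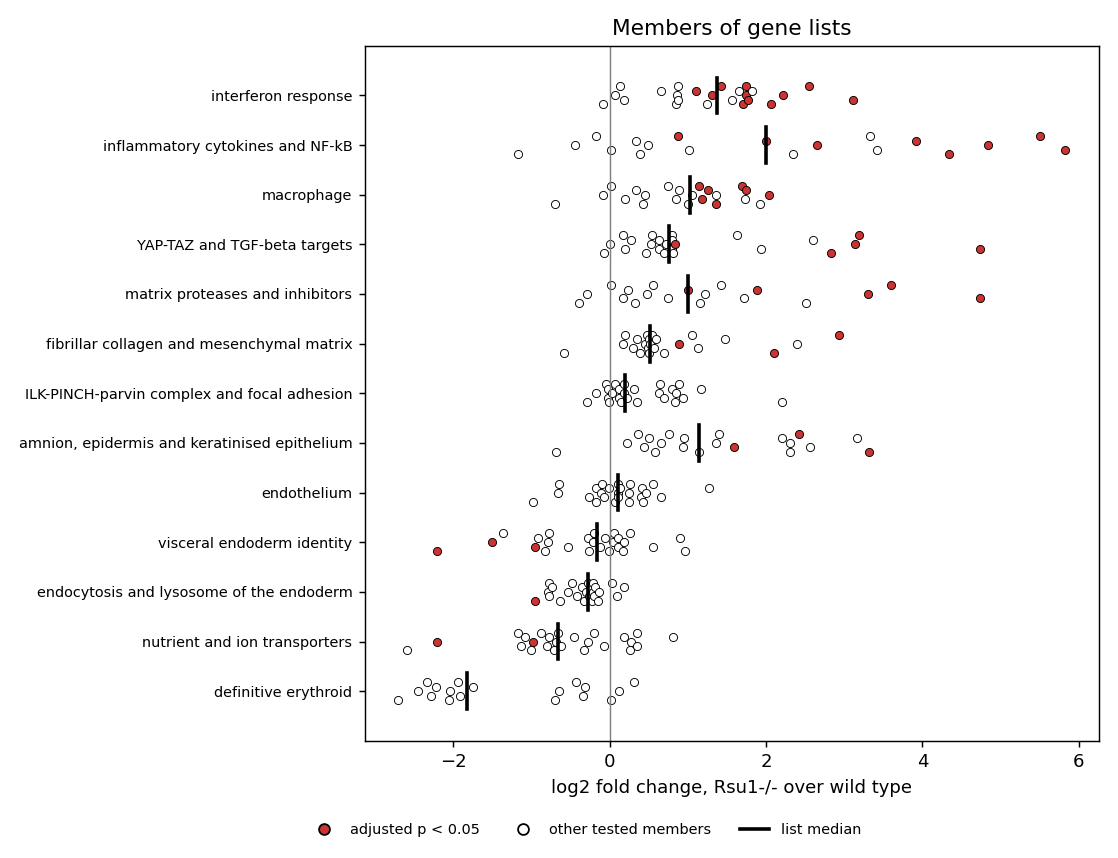
Log2 fold change of Rsu1-/- over wild type (x axis) for the tested members of 13 gene lists (y axis), 1 point per gene. Red points passed an adjusted p of 0.05 and black bars mark list medians. The inflammatory cytokine median lies farthest to the right, a place it loses without Rsu1-/- replicate 3 (1.00 against 1.55 for interferon), and the definitive erythroid median, at −1.83, farthest to the left, where no point is red.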

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

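The tests of wild-type replicate 2, of the macrophage share, of the library with Xist, of chromosome 2, of the endoderm share and of transcript length were chosen only after the result was seen.

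Xist, which was not among the genes tested, had 18828 counts in Rsu1-/- replicate 3 and 2 to 10 counts in the other 5 libraries. That replicate had 0, 0, 2 and 0 counts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. Each of the other 5 libraries had at least 265 counts of each. By these genes Rsu1-/- replicate 3 was the only female sample and the other 5 were male, so sex was not balanced between the groups. Groups of 3 were too small to test single libraries for standing apart. Of the 10 splits of the 6 libraries into 3 and 3, the genotype split gave 434 genes and the highest of the other splits 0, so 1 split reached that count, and 10 splits are too few for a share below 0.05.

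Of 21 amnion and epidermis genes 3 rose in Rsu1-/-, and the list call was lost (adjusted p = 0.257 with an estimated correlation). More of the tissue that wild-type replicate 2 lacks stayed open. For this, 33 genes were chosen for being at least 10-fold lower in that library than in the other wild-type libraries. Their median log2 ratio in Rsu1-/- over wild-type replicates 1 and 3 was 0.13, against 0.81 for the amnion list. The interval of the 33-gene median, −0.187 to 0.563, lay below 0.81, so by their medians these genes lay lower than the list. However, they ran from −2.68 to 4.05 with an SD of 1.18, and the rule of this test asked for a gap larger than that SD. Epidermis or another stratified epithelium in the dissections also stayed open, although Trp63, a regulator of stratified epithelia, had 0 counts in all 6 libraries. The median gain of 14 genes listed as abundant in stratified epithelium, 4 of them also on the amnion list, was 0.80% of the gain of Krt14. That was under the 10% set beforehand. Its interval reached 15.1%, so the bound was not met beyond its spread, a requirement that the prediction had not named. The 14 genes differed widely. Krt5, Krt15 and Dsp gained 53.1%, 30.8% and 54.5% of the gain of Krt14, while Krt1, Lgals7 and Krt10 had 0.033, 0.37 and 0.88 CPM in Rsu1-/-. A response of the yolk sac epithelium to the loss of Rsu1 may also account for the rise and was not tested apart from these.

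Of 24 interferon genes 11 and of 22 macrophage genes 7 rose in Rsu1-/-. Both list calls were lost with an estimated correlation (camera adjusted p = 0.257 for each) and kept with fry (adjusted p = 0.0376 for interferon and 0.0257 for macrophage). The library with Xist was not the sole source, since the median log2 fold change of the interferon list was 1.55 without it and 1.37 with it, although only 2 members then passed. A segment of another strain around Rsu1 stayed open: 0% of the 11 interferon genes that passed lay on chromosome 2, where 0.829 would be expected, too few to decide, and such a segment could act on genes elsewhere. A larger macrophage share alone cannot be told apart from an interferon response: the interferon median exceeded the macrophage median by 0.34, with an interval of −0.25 to 0.93. An effect of genotype, or of an infection or litter that differed between the groups, may account for it, and infection and litter were not tested.

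Visceral endoderm and transporter lists were called lower in Rsu1-/- with camera's preset correlation. Both calls were lost with an estimated correlation (camera adjusted p = 0.303 and adjusted p = 0.262) and with fry (adjusted p = 0.0692 and 0.0542). They held with other size factors, the filter on CPM, removal of globin and mitochondrial genes and the replicate block. Loss of long transcripts over all genes was argued against. The Spearman correlation of exonic length with log2 fold change over genes was 0.0246 (interval 0.00929 to 0.0396), not negative. The lower genes had a median length of 4066 bases against 4049 for tested genes. Members of the endoderm and transporter lists were not tested apart for length, so such a loss within these lists stayed open. A lower share of visceral endoderm cells alone cannot be told apart from lower expression within them. Without Krt8, Krt18 and Cdh1, which other epithelia share, a common log2 shift of −0.4 left Gata4 and Slc2a2 apart (edgeR, adjusted over the list) and 0 other members, and genes among the calls that make up the pattern do not exclude a lower share, although at least 2 other members were apart from each shift without wild-type replicate 3. Lower expression in endoderm cells of Rsu1-/- may account for the pattern, alone or with a lower share, as a hypothesis left open.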

How the results depend on the processing

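The length correction, the recovered reads and the list counts without single libraries were chosen after seeing the data. The number of changed genes was 313 to 456 under the other scalings, limma-voom, the robust fit, the stricter filter, removal of globin and mitochondrial genes, the replicate block, the 2-fold threshold, omission of X and Y genes, the length correction and the recovered reads. All 434 genes kept their sign in every setting that tested them, which their non-overlapping groups all but fixed in advance. DESeq2 called 1565 genes (839 higher, 726 lower). On simulated counts it recovered 58% of 2-fold changes against 29% for edgeR, with 45 false calls among 187 against 8 among 119. Few simulated genes were changed and no simulated library stood apart, so these shares do not show how many of the 1565 calls are false. Without a filter 1350 genes passed (795 higher, 555 lower) of 28584 tested; the cause was not tested.

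Leaving out 1 library gave 0 to 245 changed genes, 0 to 154 higher and 0 to 91 lower. Without wild-type replicate 1 edgeR called 0 genes, with 2532 at an unadjusted p below 0.05 and a smallest adjusted p of 0.0611. Fewer samples enter these fits, and which property of a library matters was not tested. The Rsu1 log2 fold change ranged from −1.38 to −1.24 and lost its call without wild-type replicate 1 or Rsu1-/- replicate 3. Of 72 other named genes past the threshold, 72 lost the call without wild-type replicate 1 and 64 without Rsu1-/- replicate 3.

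Lists called higher numbered 21, 10 with fry and 0 with an estimated correlation. Lists called lower numbered 8, and 0 with either. Fry kept 9 of the 29 calls, and its other call was the growth factor list (fry adjusted p = 0.0257), which camera had not called. Leaving out 1 library gave 19 to 21 higher and 4 to 9 lower. Signs turned, with no call in any fit, for Hbb-y (−0.14 to 1.73), Hba-x (−0.28 to 1.13), Rhox6 (−0.35 to 0.14), Ddx3y (−1.04 to 0.061) and mt-Atp8 (−0.98 to 0.14), as log2 fold changes with single libraries left out.

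Pairing by replicate number was not evident: deviations of same-numbered libraries correlated at −0.058, 0.0151 and 0.203. The last was the highest among pairs of a wild-type and an Rsu1-/- library. So few values cannot exclude pairing by litter or batch. With the number as a block 353 genes passed, 248 of them among the 434. Depth limits genes near the filter, such as Hamp with 4 wild-type counts.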

Other observations

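The solute carrier test below was written before its result was seen, after transporters had appeared among the largest falls, and its repeats without single libraries were chosen only after the result was seen.

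A few genes of other blood cell lists also rose. Runx1, a transcription factor of blood stem and progenitor cells (chromosome 16, 92601466 to 92826149), went from 10.6 ± 1.92 to 49.7 ± 13.7 CPM (4.70-fold, adjusted p = 0.0139, edgeR) and was the 1 of 12 progenitor genes to pass (3 rose when adjusted over the list alone; camera adjusted p = 0.0156, adjusted p = 0.286 with an estimated correlation), a list call lost without Rsu1-/- replicate 2 (adjusted p = 0.207). Of 8 megakaryocyte and platelet genes Thbs1 and Pf4 rose, 3.58-fold and 3.24-fold (4 rose when adjusted over the list alone; camera adjusted p = 0.0175, adjusted p = 0.257 with an estimated correlation), although Thbs1 and Pf4 are also made by other cells and the list call was lost without Rsu1-/- replicate 3 (adjusted p = 0.0532). Ppbp, on the same list, had 42.2, 0.287 and 30.5 CPM in wild-type replicates 1 to 3. It had 293.5, 406.3 and 1109 CPM in the Rsu1-/- replicates but did not pass. In all, 6 members had positive and 2 negative log2 fold changes. Of 5 mast cell and lymphocyte genes 0 passed and all 5 had positive log2 fold changes (4 rose when adjusted over the list alone; camera adjusted p = 0.00425, adjusted p = 0.257 with an estimated correlation). Of 24 growth factor genes Igfbp5 and Egfr, the receptor of epidermal growth factor, rose 2.12-fold and 2.22-fold (5 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.0712). The imprinted transporter Slc22a3 fell 3.24-fold, the 1 of 23 imprinted genes to pass (1 when adjusted over the list alone; camera adjusted p = 0.0151, adjusted p = 0.286 with an estimated correlation), a list call lost without Rsu1-/- replicate 2 (adjusted p = 0.104).

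Few markers of tissues next to the yolk sac, or of neutrophils, passed over all genes. Of 10 decidua and uterus genes 0 passed and 8 had positive log2 fold changes, with a median of 0.65 (4 rose when adjusted over the list alone; camera adjusted p = 0.0204, adjusted p = 0.257 with an estimated correlation). Of 20 parietal endoderm genes Plat rose and Lgals2 fell 2.50-fold (4 rose and 3 fell when adjusted over the list alone; camera adjusted p = 0.049, adjusted p = 0.282 with an estimated correlation). Of 11 hepatocyte genes Hamp rose and Cps1 fell (2 rose and 5 fell when adjusted over the list alone; camera adjusted p = 0.036, adjusted p = 0.257 with an estimated correlation). The parietal endoderm call was lost in 4 of the 6 fits without 1 library (adjusted p = 0.0728 without wild-type replicate 2, 0.14 without wild-type replicate 3, 0.189 without Rsu1-/- replicate 2 and 0.0594 without Rsu1-/- replicate 3) and with the replicate number as a block (0.0539), and the hepatocyte call in 3 (0.0954, 0.0922 and 0.0594 without wild-type replicate 2 and Rsu1-/- replicates 2 and 3). Of 6 neutrophil genes 0 passed and all 6 had positive log2 fold changes (2 rose when adjusted over the list alone; camera adjusted p = 0.00497, adjusted p = 0.257 with an estimated correlation).

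Several genes with small p lay outside the naming rule and were chosen after their values were seen. Ifitm3, an interferon-induced membrane protein, rose 3.36-fold (24.3 ± 1.15 to 81.6 ± 7.85 CPM, adjusted p = 0.00885, edgeR). Cldn18, a tight-junction claudin, rose 19.9-fold from 45 counts over the wild-type libraries. Acss1, a mitochondrial acetyl-CoA synthetase, and Hmgcs2, the mitochondrial enzyme of ketone body synthesis, fell 2.71-fold and 3.39-fold.

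Solute carrier genes, the family of membrane transporters with Slc symbols, made up 18 of the 185 lower genes (9.73%) and 271 of the 15610 tested (1.74%), an odds ratio of 6.46 (Fisher's exact test, one-sided, p = 3.74e-09, with genes not independent). They made up 4 of the 249 higher genes (odds ratio 0.923, Fisher's exact test, two-sided, p = 1). The count rested on single libraries: without wild-type replicate 1 no gene was lower, and without Rsu1-/- replicate 3 it was 1 of 4 (Fisher's exact test, one-sided, p = 0.0661). Without any other 1 library 6 to 10 solute carriers were among 55 to 91 lower genes, with odds ratios of 4.90 to 8.57. The hypothesis that the lower genes hold more solute carriers than chance gives was met by this test with all 6 libraries, on the data in which it was noticed.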
